A study of Mus musculus with 8 samples.

How the data were processed

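Chromatin from the cerebral cortex of mouse embryos at embryonic day 15.5 was profiled by ChIP-seq, in which an antibody pulls down DNA bound by a protein or a modified histone and the recovered DNA is sequenced. The antibody recognised methylated lysine 4 of histone H3, written H3K4me in the labels, and its catalogue entry is for the monomethylated form, a mark of enhancers and of promoter flanks. Per the labels' protocols, the chromatin was native (not crosslinked) and was cut with micrococcal nuclease before precipitation. There were 4 ChIP libraries, 2 from control embryos that carry floxed Prdm16 alleles without Cre (WT) and 2 from embryos that also carry Emx1-Cre (cKO). The 4 matching input libraries were not analysed here.

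The authors deposited 1 list of broad peaks per ChIP library, so peaks were called on each library and not on pooled replicates. Per the submitters' processing notes, FastQC, cutadapt, Bowtie2 2.2.8 and MACS2 2.1.1 were used with the mm10 build; the calling options, read filters and use of the inputs are not given in the sources used here. Each deposited line gives a peak's coordinates, a score, a fold enrichment over the caller's background (a ratio), and a −log10 p-value and a −log10 q-value, all as the authors' caller wrote them. The deposited score is 10 times the −log10 q-value cut to a whole number in nearly all peaks. The smallest −log10 q-value was between 1.30 and 1.32 in every list. Fold enrichment, p and q are the authors' own values for each peak and were used to describe, rank or filter peaks within 1 list. Median fold enrichment and the smallest −log10 q-values were also set side by side between the lists of the genotypes. The deposited lists hold no read counts, so the sequencing depth is unknown and no counting interval was computed. A library that was sequenced more deeply, or in which precipitation worked better, gives more and wider peaks, and every measure based on called peaks inherits this.

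Peaks on chromosomes 1 to 19, X and Y were kept. Intervals were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The interval code was tested on simulated data (150 checks against base-by-base counting, 0 mismatches) and gave the same Jaccard index as bedtools 2.31.1 for the pair of WT libraries (0.667). Gene names and spans came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 represents. That table has no strand, exons or transcription start sites, so promoter and exon shares, the planned window on gene starts, and the planned motif search, which needs the genome sequence, were not run.

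A genotype-specific region was an interval of at least 200 bp covered by peaks in both libraries of 1 genotype with no peak base in either library of the other. The same count was made for the 2 other ways of splitting the 4 libraries into pairs. A gene locus was the span of a protein-coding gene plus 10 kb on either side. Of 21631 such loci with a unique symbol, 76.3% overlapped another, so neighbouring genes share peaks and their values are not independent. The bases covered by peaks in each locus were converted to log2(bases + 500), loci with a mean under 1000 covered bases were left out, and each library was centred on its median over the 14941 loci kept. A log2 difference is on this scale and understates the change of thinly covered loci. Genotypes were compared with limma 3.58.1 in R 4.3.3 (eBayes with a trend, 2 libraries against 2, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated data for this comparison with 14941 loci, the fit recovered 8 of 50 loci changed by 0.5 on the log2 scale, 20 of 50 changed by 1, 50 of 50 changed by 2 and 48 of 50 changed by 4, with 14 false calls. Recovery may be lower at thinly covered loci of the real data. There, Lpcat2b differed by 2.54 ± 0.44 (SE) and did not pass (limma adjusted p = 0.407).

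The tests, the 12 genes always given and 22 gene lists (404 entries, 403 with a locus) were fixed before the data were examined. They covered cell types of the cortex, other cell types a cortical lysate could hold, signalling pathways, chromatin enzymes and housekeeping genes. Lists were compared between genotypes with camera (preset correlation 0.01) and with an estimated correlation, and fry, which tests whether the loci of a list move on balance in 1 direction, was run beside them. The level of coverage of a list was its median covered share of the locus, set as a percentile among 10000 random lists matched on locus length. Single values per library were compared with a two-sided exact permutation test, which for 2 against 2 cannot give a p below 0.333. The rule for the genes named had 5 parts: the 12 genes always given, 10 loci per direction ordered by the locus test or, where too few pass, by size of difference among those at unadjusted p under 0.05 with no overlap between genotypes, the 3 members of each list with the largest difference, the 10 most covered loci of at least 20 kb, and the 5 longest regions specific to each genotype. The rule reached more genes than could be described, so list members are named only for lists that camera called, a choice made after the data were seen. Some genes that the rule gave are not reported here.

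The alternatives were peaks with a −log10 q-value of at least 3, the 66476 strongest peaks of each list by the authors' −log10 p-value (equal number), other overlap and length criteria for regions, other pseudocounts, filters and scalings, the replicate number as a block, and each library left out. After the data were seen, lists cut in the same order to an equal covered length, gene spans alone or with 25 kb on either side, and cyclic loess scaling were added. The replicate numbers in the labels are not said to mark a shared litter or day. Nothing in the labels says whether replicates came from separate embryos, so p-values measure the spread between these libraries, which may be technical.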

Results

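The study mapped H3K4 methylation in the cortex of control embryos and of embryos in which Prdm16 was deleted by Emx1-Cre, a driver active in the progenitors of the dorsal telencephalon. Prdm16 encodes a zinc-finger transcriptional regulator expressed in radial glia, the neural stem cells of the cortex. The comparison asks where the mark differs between the genotypes. There were 2 libraries per genotype, each with its own list of broad peaks. The lists held 75314 peaks in WT replicate 1, 66476 in WT replicate 2, 80519 in cKO replicate 1 and 82683 in cKO replicate 2. The read depth behind them is unknown.

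In the cortex at this age the mark was concentrated over genes of neural progenitors and neurons. Of 21631 protein-coding loci, 70.3% held peak bases in all 4 libraries and 22.5% in none. Intermediate progenitor genes (18 measured) had the highest list value, with a median of 42.7% ± 5.32 of the locus covered (SD, n = 4 libraries), against 7.46% in random lists of matched locus length. Radial glia genes stood at 33.4% ± 4.26 against 6.09%, and genes of newborn projection neurons at 32.7% ± 3.35 against 6.45%. Notch pathway genes, which hold progenitors in an undifferentiated state, had 31.6% ± 4.99 covered. Upper layer neuron genes had 24.9% ± 0.840 and deep layer genes 22.1% ± 3.68. The lists for Wnt signalling (23.99% ± 3.03), BMP and TGF-beta signalling (18.6% ± 2.91) and neuronal migration and guidance (17.3% ± 2.54) were also above the 99th percentile of random lists in every library. Genes of cortical interneurons (20.5% ± 4.70) and Cajal-Retzius cells (22.2% ± 5.05), neurons that reach the cortex from other sources, lay above the 99th percentile as well, although the Cajal-Retzius list fell to percentile 91.5 in 1 library with stricter peaks.

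Lists for non-neural cell types did not stand above random lists in the same way. Microglia genes had a median of 4.31% ± 1.42 covered (SD, n = 4 libraries), between percentiles 11.9 and 27.7 of matched random lists. Erythroid genes stood at 2.48% ± 0.694 and skeletal muscle and liver genes at 2.51% ± 0.658, the latter between percentiles 6.52 and 9.05. Meningeal genes (6.84% ± 1.77), endothelial and pericyte genes (7.49% ± 1.58), choroid plexus and hem genes (9.60% ± 1.58), brown fat genes (8.71% ± 3.86) and cell cycle genes (11.5% ± 2.77) did not pass the 95th percentile in all libraries. Housekeeping genes (14.8% ± 3.85), the PRDM family and histone methylation enzymes (11.6% ± 2.23) and genes of oligodendrocyte precursors and astrocytes (17.2% ± 1.92) did, the last of these not with stricter peaks (lowest percentile 88.4). In all, 14 of the 22 lists were above the 95th percentile in every library. These percentiles describe the libraries and are not tests.

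Loci of at least 20 kb were ranked by coverage, and the 10 kb on either side of each gene makes nearly all loci that long. The most covered was Sox2, the transcription factor that maintains neural stem cells. Peaks lay over 91.5% ± 2.73 of its locus (SD, n = 4 libraries), which is mostly flank (chromosome 3, 34649995 to 34652461 for the gene, GRCm38). Nfix, a nuclear factor I gene that acts in radial glia, followed with 90.1% ± 2.98, and Neurod2, a bHLH factor of projection neurons, with 87.2% ± 8.92. Pipox (85.9% ± 5.25), Zfhx2 (83.1% ± 6.94), Gm33099 (78.8% ± 6.96, beside Neurod2), Enc1 (78.6% ± 5.51), Foxo6 (78.2% ± 2.79), Flrt1 (78.1% ± 3.23) and Igsf8 (77.9% ± 4.90) completed the 10. Protein-coding gene spans held 63.7% ± 0.340 of covered bases in WT and 63.4% ± 0.0202 in cKO (SD, n = 2 each), compared with 39.4% of the bases between the first and last annotated genes of the chromosomes. The difference turned to 0.126 with equal numbers of peaks, and was −0.511 without WT replicate 1 and −0.0313 without WT replicate 2. The difference of −0.271 percentage points had an exact permutation p of 0.333, the smallest possible with 2 against 2.

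More of the genome was called in the cKO libraries. Peaks covered 157 Mb ± 12.7 in cKO and 122 Mb ± 11.6 in WT (SD, n = 2 each), a ratio of 1.29, and both cKO lists exceeded both WT lists. The number of peaks was 81601 ± 1530 in cKO and 70895 ± 6249 in WT. The difference of 10706 peaks was 6287 without WT replicate 2 and 15125 without WT replicate 1. Median peak width was 1290 bp ± 66.5 against 1170 bp ± 2.12, as the caller drew the peaks. Median fold enrichment was 3.90 ± 0.127 against 3.93 ± 0.308 and overlapped between genotypes. The exact permutation p was 0.333 for number, covered length and width, and 1 for fold enrichment, two-sided, and this test cannot go below 0.333 with 2 against 2.

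**Figure D1:**
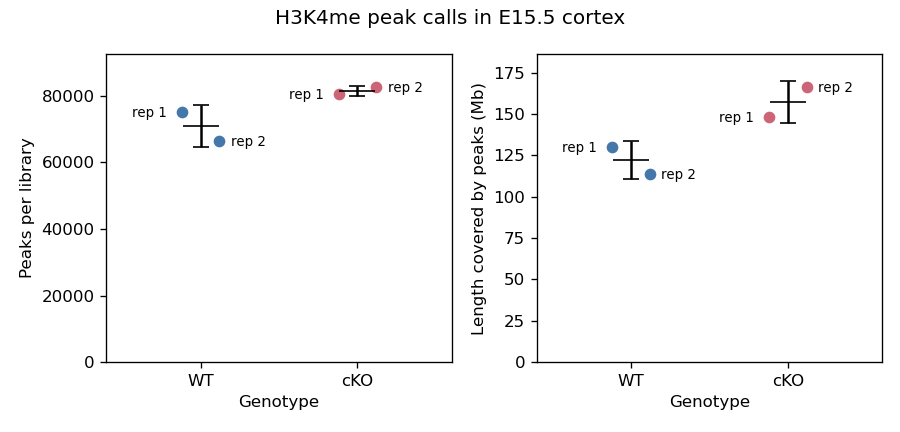
Number of peaks (left) and length covered by peaks in Mb (right) in each H3K4me library; points are libraries, the horizontal mark is the mean and the bar the SD over 2 libraries. Both cKO libraries lie above both WT libraries, with 148 and 166 Mb covered against 130 and 114 Mb.

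The 4 libraries shared most of the mark. Of 61195 intervals covered in both WT libraries, 94.8% touched a peak in both cKO libraries, 4.29% in 1 of them and 0.949% in neither. The bases common to both WT libraries were 91.5% covered in both cKO libraries. In the other direction, 78.0% of 72333 intervals common to the cKO libraries touched a peak in both WT libraries and 7.73% in neither. The Jaccard index of covered bases was 0.667 between the WT libraries and 0.676 between the cKO libraries. Between genotypes it ranged from 0.580 to 0.681, so WT replicate 1 shared more with cKO replicate 1 than with WT replicate 2. The within-genotype mean exceeded the between-genotype mean by 0.0365, less than the SD of the between-genotype pairs (0.0428), compared with −0.0248 and −0.0117 for the 2 other ways of pairing the libraries. With 3 pairings no share under 0.05 can be reached.

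Regions specific to a genotype numbered 5591 for cKO and 581 for WT. They were short and weak: the median length was 452 bp in cKO-only and 378 bp in WT-only regions, against 1037 bp for intervals covered in all 4 libraries. The median −log10 q of the cKO-only peaks, as called by the authors, was 2.65 and 2.60 in cKO replicates 1 and 2, where all peaks had 4.14 and 3.71. The 5 longest cKO-only regions lay in Exoc6b (chromosome 6, 84742602 to 84747753, 5152 bp), 49218 bp from Dad1 (chromosome 14, 54182454 to 54186266), in Gnao1 (chromosome 8, 93851058 to 93854626), in Sergef (chromosome 7, 46472965 to 46476359) and in Pitpnc1 (chromosome 11, 107457242 to 107460479). Gnao1 encodes a G protein alpha subunit abundant in brain. The 5 longest WT-only regions lay 26673 bp from Acad9 (chromosome 3, 36119531 to 36121408, 1878 bp), and in Crybg1 (chromosome 10, 43973268 to 43974891), Mllt3 (chromosome 4, 87792869 to 87794463), Patj (chromosome 4, 98660354 to 98661789) and C330007P06Rik (chromosome X, 36863530 to 36864920). Coding gene spans were touched by 55.2% of cKO-only and 51.5% of WT-only regions, compared with 63.2% of shared intervals.

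The count and its direction depended on how much was called. Splits of the same libraries by replicate number gave 1722 and 698 regions, and the crossed split 2282 and 997. With stricter peaks the cKO-only and WT-only counts were 6307 and 290. With equal numbers of peaks the cKO-only and WT-only counts were 2830 and 1768. With lists cut to equal covered length they were 560 and 6718, so the direction turned. Of the 5591 cKO-only regions, 307 were also cKO-only with equal numbers and with equal length, and 254 of the 581 WT-only regions were also WT-only under both. With stricter peaks these counts were 934 and 25.

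**Figure D2:**
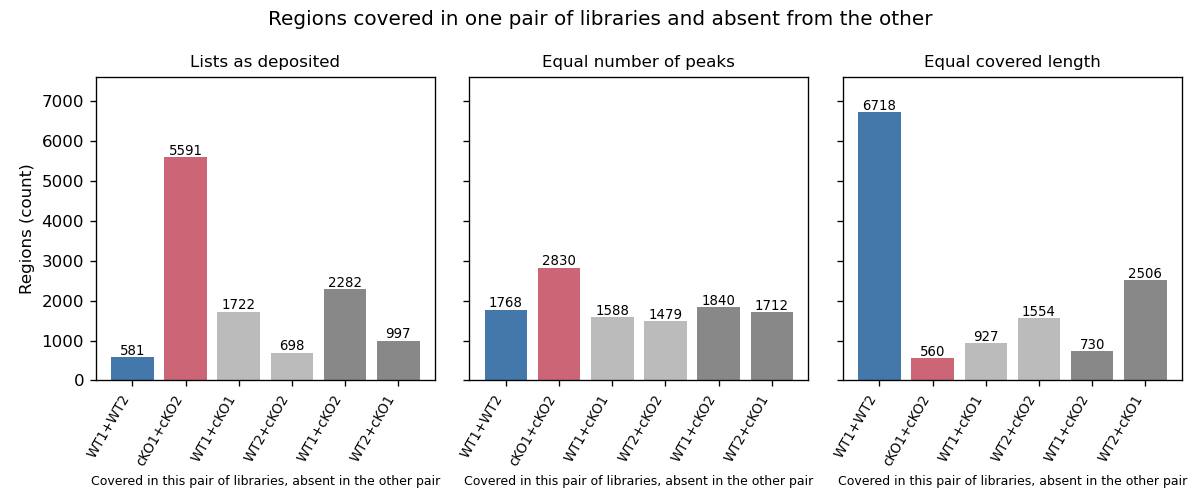
Number of regions covered in 1 pair of libraries and absent from the other pair, for the genotype split (coloured) and the 2 other splits (grey), with lists as deposited, cut to an equal number of peaks and cut to an equal covered length. The cKO-only count of 5591 exceeds the WT-only count of 581 in the first panel and is below it, 560 against 6718, in the third.

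Across single gene loci no difference between the genotypes passed the threshold. limma called 0 of 14941 loci higher and 0 lower in cKO (smallest adjusted p = 0.407), while 830 loci were higher and 663 lower at an unadjusted p under 0.05, where 747 are expected in all. The other splits of the libraries gave 369 and 741 loci at that level. With cyclic loess scaling 1013 loci were higher and 360 lower at that level. The balance turned with equal covered length (535 higher, 651 lower) and with 25 kb on either side of the gene (871 higher, 987 lower). Without centring these counts were 3196 and 10, because the median log2 difference over loci was then 0.35. Differences are given after centring on the library medians, which left the median locus at −0.038. A value between −0.038 and 0 therefore lies above the median locus. Leaving out WT replicate 1 gave 95 higher and 3 lower calls, and leaving out WT replicate 2 gave 8 higher calls. Only Veph1 was among the higher calls of both.

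The targeted gene, Prdm16 (chromosome 4, 154316122 to 154637360), was broadly marked in every library, with 154 and 144 kb of its 341 kb locus under peaks in WT replicates 1 and 2 and 171 and 182 kb in cKO. Its log2 difference was −0.14 ± 0.066 (SE, 2 libraries per genotype; limma adjusted p = 0.518), and turned to 0.25 without centring and 0.16 with equal covered length. The labels do not give the deleted exon, and broad peaks over the whole gene do not check the deletion.

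Pdzrn3, which encodes an E3 ubiquitin ligase and is a published target of PRDM16 repression in this mutant, had more of its locus under peaks in both cKO libraries. Peaks covered 55.1 and 47.8 kb in WT replicates 1 and 2, and 79.7 and 88.4 kb in cKO replicates 1 and 2, in a locus of 248 kb on chromosome 6. The log2 difference was 0.32 ± 0.073 (SE), with a limma p of 0.00244, an adjusted p of 0.407 over all loci and of 0.0293 adjusted over the list alone, here the 12 genes always given. Because published work on this mutant prompted its choice, the second value is not independent evidence. The other splits of the libraries gave differences of −0.011 and 0.015. The locus held 22 and 18 peaks in WT and 26 and 27 in cKO. In it, 4 regions were cKO-only, the longest of 905 bp (101283934 to 101284838). The difference was positive in all 16 alternatives, from 0.27 to 0.70. The replicate block and the fits with 1 library left out could hardly turn the sign, because both cKO values exceeded both WT values. The limma p of Pdzrn3 adjusted over the 12 genes ranged from 0.00395 to 0.249 and missed the threshold in 6 alternatives. These were stricter peaks, equal covered length, the replicate block (adjusted p = 0.0999), and the fits without WT replicate 2 (adjusted p = 0.0896), cKO replicate 1 (0.0857) or cKO replicate 2 (0.185).

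**Figure D3:**
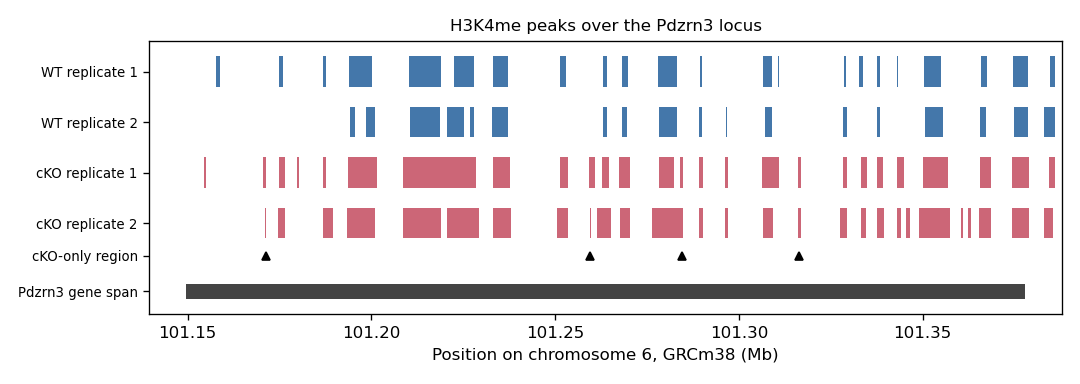
Peaks of each library over the Pdzrn3 locus (chromosome 6, GRCm38, position in Mb), with cKO-only regions as triangles and the gene span as a bar. The cKO libraries have 26 and 27 peaks there and the WT libraries 22 and 18.

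The other genes of this set reported here, 9 in all, had negative differences after centring. Bcl11b, the deep layer factor that directs subcerebral projection neurons, stood at −0.30 ± 0.084 (SE; limma adjusted p = 0.435 over all loci and 0.0429 adjusted over the list alone). It turned to 0.081 without centring and to 0.041 with equal covered length, and its limma p adjusted over the 12 genes missed the threshold in 12 of 16 alternatives (range of adjusted p 0.0175 to 0.808). Values for the progenitor factors were −0.34 ± 0.12 for Sox2, −0.32 ± 0.14 for Pax6, −0.34 ± 0.14 for Hes5, −0.27 ± 0.12 for Eomes and −0.20 ± 0.12 for Neurog2. Sox2 had 20.9 and 19.6 kb of its 22.5 kb locus under peaks in WT replicates 1 and 2, and 20.9 and 20.8 kb in cKO. Even full coverage in cKO would have left its centred value negative, so its sign is not evidence of a loss. The neuronal factors Cux2 (−0.19 ± 0.087), Pou3f2 (−0.31 ± 0.16) and Tbr1 (−0.24 ± 0.11) were similar in size, and these 8 genes had adjusted p-values between 0.474 and 0.591 over all loci. Without centring all 9 were positive, between 0.039 and 0.19. Single libraries moved Pax6 (−0.15 without WT replicate 2, −0.50 without WT replicate 1), Pou3f2 (−0.12 without cKO replicate 2, −0.51 without cKO replicate 1), Neurog2 (−0.11 without WT replicate 2) and Cux2 (−0.12 without cKO replicate 2) by over 1.5 times. Prdm16 was at −0.083 without WT replicate 2.

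The loci with the largest differences were thinly covered, and none passed the test (limma adjusted p between 0.407 and 0.474 for those named). Lpcat2b had no peak in either WT library and 3.38 and 3.198 kb under peaks in cKO. A930007A09Rik, Stx17, Gm33153 and Ikbkg were also without WT peaks, with 2.07 to 3.50 kb in the cKO libraries. Fam184a, Clcn3, Il1rapl2, Coq7 and Far1 had at most 1.47 kb in a WT library and at least 2.27 kb in each cKO library. In the other direction Gm38499 had 2.60 and 1.61 kb in WT and 0.741 and 0.377 kb in cKO. Gm52875, Cyp2d11, Cnot6l with the overlapping Gm52799, Chmp3, Jrk, Gm51963 and Dcp2 had log2 differences between −1.44 and −1.22. Single libraries moved Clcn3 (1.47 without WT replicate 2), Gm52875 (−0.90 without cKO replicate 1) and Dcp2 (−0.51 without cKO replicate 2).

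As groups, 8 of the 22 gene lists were lower in cKO relative to the median locus by camera with its preset correlation, and none was higher. None of these calls held with an estimated correlation (adjusted p between 0.709 and 0.778), and fry called 0 lists (adjusted p between 0.319 and 0.417 for these 8). The estimated correlation of Notch (−0.0074) and deep layer genes (0.0022) lay under the preset 0.01. Their lost calls therefore do not come from correlation between loci, and with 2 libraries per genotype that version has little power. The other called lists had estimated correlations from 0.075 (upper layer) to 0.32 (radial glia), above the preset. Correlation between loci may account for their lost calls, so these calls depend on the preset value. All p-values of single lists are from the preset correlation. All 8 medians were above 0 without centring, between 0.13 and 0.22. No member of any list passed over all loci. Radial glia genes had a median log2 difference of −0.25, with 21 of 25 members negative (camera adjusted p = 0.00804). The examples were Id4 (−0.58 ± 0.22, SE), Tnc (−0.46 ± 0.22) and Hes1 (−0.45 ± 0.13), and 2 members passed adjusted over the list alone, Gli3 (−0.38 ± 0.082) and Notch2 (−0.37 ± 0.091), named after their values were seen and at 0.00026 and 0.014 without centring. Intermediate progenitor genes had a median of −0.25, with 16 of 17 negative (adjusted p = 0.0110), led by Neurod4 (−0.71 ± 0.37), Mfap4 (−0.36 ± 0.14) and Insm1 (−0.35 ± 0.15). Notch signalling genes had −0.23, with 15 of 16 negative (adjusted p = 0.0282). Among these Hey2 stood at −0.56 ± 0.27 and Hes1 at −0.45, and Jag2 at 0.49 ± 0.29. Wnt signalling genes had −0.18, with 17 of 19 negative (adjusted p = 0.0214), and the receptors Fzd1 (−0.65 ± 0.29), Fzd5 (−0.40 ± 0.19) and Fzd10 (−0.38 ± 0.17) as examples.

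Neuronal lists had negative medians too, with calls that likewise did not hold with an estimated correlation. Upper layer genes had a median of −0.19, with 15 of 17 negative (camera adjusted p = 0.0326), among them Inhba (−0.59 ± 0.16, SE), Pou3f1 (−0.38 ± 0.16) and Lpl (−0.36 ± 0.19). Deep layer genes had −0.16, with 15 of 18 negative (adjusted p = 0.0432), among them Foxp2 (−0.51 ± 0.16), Etv1 (−0.39 ± 0.17) and Fezf2 (−0.34 ± 0.12). Genes of newborn projection neurons had −0.18, with 17 of 19 negative (adjusted p = 0.0432). Their examples were the bHLH gene Neurod1 (−0.46 ± 0.18), the netrin receptor gene Unc5d (−0.42 ± 0.093) and the slit receptor gene Robo2 (−0.41 ± 0.12), of which Unc5d passed adjusted over the list alone (adjusted p = 0.0351) and was at −0.039 without centring. Oligodendrocyte precursor and astrocyte genes had −0.26, with 9 of 11 negative (adjusted p = 0.0432), among them Gfap (−0.40 ± 0.17), Nkx2-2 (−0.39 ± 0.20) and Aldh1l1 (−0.34 ± 0.20).

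With cyclic loess 0 lists were called, with medians of the 8 lists between −0.21 (oligodendrocyte precursors and astrocytes) and −0.085 (deep layer) and camera adjusted p from 0.0564 up. With equal covered length the 1 list called was that of the meninges. The upper layer (−0.17) and newborn neuron (−0.15) medians were then about as large as before, with a wider spread over members, and the other 6 lay between −0.065 and 0.024. Many member values rested on 1 library. Neurod4 was at −0.24 without WT replicate 2 and −1.18 without WT replicate 1, Fzd1 at −0.31 and −0.99, and Tnc at −0.74 and −0.18 in the same order. Hey2 ranged from −0.85 (without cKO replicate 2) to −0.27 (without cKO replicate 1). Without cKO replicate 2, Id4 was at −0.36, Insm1 at −0.23, Foxp2 at −0.28 and Robo2 at −0.23. Without cKO replicate 1, Nkx2-2 was at −0.22 and Pou3f1 at −0.23. Neurod1 (−0.27) and Jag2 (0.28) were smaller without WT replicate 2, and Aldh1l1 (−0.22) without WT replicate 1.

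The remaining 14 lists did not pass. For comparison, the median log2 difference over all tested loci was −0.038 after centring. Medians were −0.096 for cortical interneurons, −0.026 for Cajal-Retzius cells, −0.14 for choroid plexus and hem, −0.079 for microglia, −0.063 for endothelial cells and pericytes, −0.15 for the meninges, 0.037 for erythroid cells and −0.26 for skeletal muscle and liver. They were 0.00043 for the brown fat programme, −0.086 for neuronal migration and guidance, −0.026 for the cell cycle, −0.098 for BMP and TGF-beta signalling, −0.089 for the PRDM family and histone methylation enzymes and −0.022 for housekeeping genes (camera adjusted p between 0.245 and 0.862). The choroid plexus, endothelial, cell cycle, Cajal-Retzius and PRDM lists had means above 0 beside medians below 0, and camera placed the endothelial and cell cycle lists upward and the other 3 downward. In the migration list 2 members passed adjusted over the list alone, Pdzrn3 (adjusted p = 0.0403) and Unc5d (0.0403), in opposite directions.

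**Figure D4:**
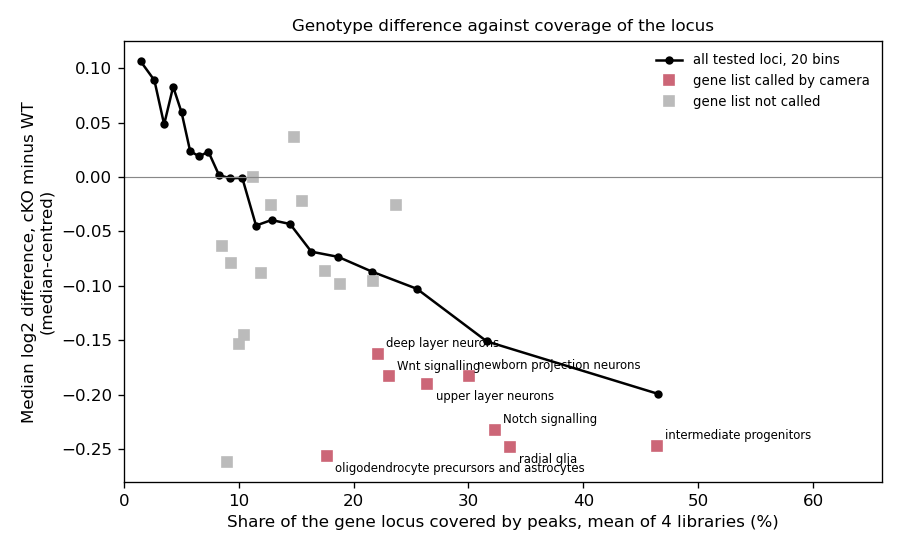
Median log2 difference in covered length, cKO minus WT after median centring, against the share of the locus under peaks (percent, mean of 4 libraries); black points are 20 bins of all tested loci and squares are gene lists, red where camera called them. The bins run from 0.11 at 1.47% covered to −0.20 at 46.5% covered, and the called lists lie at −0.16 or below.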

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

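Both results here are signals in data that the comparisons do not use, sequence outside the assembled chromosomes, and were looked at after the data were seen. A contig assigned to chromosome 4 without a position on it held 1 peak in cKO replicate 1 (position 31993 to 32326, fold enrichment 3.54) and 1 in cKO replicate 2 (31973 to 33364, fold enrichment 3.10), and 0 in each WT list. Both peaks were weak, with −log10 q-values of 2.87 and 2.21, where the medians of all peaks in these lists were 4.14 and 3.71. No explanation was tested.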

How the results depend on the processing

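The settings with equal covered length, gene spans alone or with 25 kb, and cyclic loess were chosen after the results were seen. The planned promoter window, gene start window and motif settings were not run. Without read counts, depth limits all of them. The list levels gave 12 to 14 lists above the 95th percentile. The lists lost with stricter peaks and with equal covered length were Cajal-Retzius cells (lowest percentiles 91.5 and 91.8) and oligodendrocyte precursors and astrocytes (88.4 and 90.9). The mean Jaccard index within genotypes exceeded that between them by 0.0300 to 0.0492 under 3 alternatives, differences below the SD between pairs of different genotypes (0.0341 to 0.0695), and single pairs overlapped. The cKO lists had 14158 more peaks with stricter calls and a difference of −17888 when cut to equal covered length. Setting an equal number of peaks or an equal length fixes the peak count or the length itself, so those values are not given. The difference in the share of bases in coding genes turned to 0.126 with equal numbers of peaks and 0.813 with equal length, and ranged from −0.511 (without WT replicate 1) to −0.0313 (without WT replicate 2).

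WT-only regions numbered 290 with stricter peaks, 1768 with equal numbers, 6718 with equal length, 948 when absence meant under 50% covered and 24 at a minimum of 1000 bp. The cKO-only counts in the same order were 6307, 2830, 560, 8673 and 497. Leaving out 1 library, which relaxes the criterion by construction, gave 1604 (without WT replicate 1) to 3494 (without WT replicate 2) WT-only and 8338 (without WT replicate 2) to 14219 (without cKO replicate 1) cKO-only regions.

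Loci called higher ranged from 0 to 95 and lower from 0 to 3 when 1 library was left out, the maxima without WT replicate 1, where the lone WT library is assumed to vary like the others. Lpcat2b (2.43), Fam184a (2.74), Clcn3 (3.25) and Far1 (2.38) were among those calls. The 3 lower calls were Arc, Ccdc80 and Fam171b. Every other setting called 0 loci in both directions. The count of lower lists, 8 in the report, was 0 with stricter peaks, no centring, quantile scaling, cyclic loess or an estimated correlation, 1 with equal numbers of peaks, equal length or gene spans alone, 2 with a pseudocount of 2000 bp, and 0 (without WT replicate 2) to 4 (without WT replicate 1) with 1 library left out. The replicate block gave 5 lower lists and 0 loci in either direction. Differences between replicates 1 and 2 correlated across loci at −0.0962 between the genotypes, and with 2 pairs the numbers do not pair the samples. The cause of these changes was not tested beyond the tests of called length described with the patterns.

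Without centring, the difference became positive for Prdm16 (0.25), Pax6 (0.060), Sox2 (0.039), Hes5 (0.041), Eomes (0.11), Neurog2 (0.18), Cux2 (0.19), Pou3f2 (0.075), Bcl11b (0.081), Tbr1 (0.14), Mfap4 (0.025), Insm1 (0.034), Pou3f1 (0.0079), Lpl (0.025), Fezf2 (0.049), Aldh1l1 (0.047) and Fzd10 (0.0070). List medians became 0.14 for radial glia and 0.14 for intermediate progenitors, 0.20 for newborn neurons, 0.19 and 0.22 for upper and deep layers, 0.13 for oligodendrocyte precursors and astrocytes, 0.15 for Notch and 0.20 for Wnt. Equal covered length turned Prdm16 (0.16), Sox2 (0.0022), Hes5 (0.0039), Neurog2 (0.15), Cux2 (0.067), Bcl11b (0.041), Tbr1 (0.11), Jag2 (−0.50) and the radial glia (0.022), intermediate progenitor (0.024) and Notch (0.0015) medians. Gene spans alone turned Sox2 (0.31), Pou3f2 (0.11), Jag2 (−0.16) and Fzd10 (0.17), and stricter peaks turned Lpl (1.07), Etv1 (0.45), Nkx2-2 (0.30) and Fzd1 (0.49). Leaving out 1 library moved 23 of the 55 differences by over 1.5 times and changed the sign of 0. In all 55 loci both cKO values lay beyond both WT values, so a change of sign was hardly possible. Of the 55 loci that the naming rule gave, 33 kept their direction in every alternative that tested them.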

Other observations

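The tests of Pdzrn3 against loci of like coverage and of lists matched on covered share were set before their results were seen, and the tests with equal covered length and of other splits were chosen after. Of the stretches covered without a break in all 4 libraries, the longest, 71412 bp on chromosome 8 (84698247 to 84769658), spanned Nfix with its neighbours Lyl1 and Trmt1. Next came 43812 bp over Bcl11a (chromosome 11, 24084350 to 24128161), a zinc-finger factor of projection neurons, and 43217 bp over Nfib (chromosome 4, 82451510 to 82494726), another nuclear factor I gene. A stretch of 41576 bp covered Flrt1 and Macrod1 (chromosome 19), and 39579 bp covered Pmepa1 (chromosome 2), an inhibitor of TGF-beta signalling. These were chosen after their values were seen.

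The first pattern is the excess of cKO-only regions over WT-only regions. With lists cut to equal covered length the ratio of cKO-only to WT-only regions went from 9.62 to 0.0834, far past the 1 that removing an excess of called bases would give. The cut left the cKO lists with −log10 q-values of at least 3.64 and 3.74, against 2.63 and 1.31 in WT, which by itself makes WT-only regions, so this test leaves more called bases in the cKO lists open as a cause. With equal numbers of peaks, where the cKO lists still covered 144 Mb against 118 Mb in WT, the counts favoured cKO, 2830 against 1768. With stricter peaks, where the cKO lists still covered 131 Mb against 91.4 Mb in WT, the counts were 6307 and 290. A genotype effect stays open: the genotype split gave 6172 specific regions in both directions together, and the highest of the 2 other splits 3279. It was the 1 of 3 splits with as many, and 3 splits are too few for a share under 0.05.

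The second pattern is the smaller gain in covered length of 8 gene lists in cKO relative to the median locus, called by camera with its preset correlation. None of these calls held with an estimated correlation (adjusted p between 0.709 and 0.778), and fry called 0 lists. For Notch and deep layer genes the camera p rose from 0.00513 to 0.0954 and from 0.0157 to 0.124. Their estimated correlations (−0.0074 and 0.0022) were under the preset 0.01, so correlation between loci did not cause these losses. With 2 libraries per genotype that version has little power, and these 2 losses do not decide. The other called lists had estimated correlations from 0.075 (upper layer) to 0.32 (radial glia), above the preset. Correlation between loci may account for their lost calls, so these calls depend on the preset value. Without centring the medians of all 8 were above 0, between 0.13 and 0.22. Across all loci the median log2 difference falls from 0.11 in the least covered bin to −0.20 in the most covered one, so loci already largely covered may have had less room to gain. Random lists matched on covered share had medians as low as −0.17 (for intermediate progenitors). Of the 8 lists, 2 still fell in the lowest 2.5%, radial glia (percentile 1.02) and oligodendrocyte precursors and astrocytes (percentile 1.85). The 8 had been picked as low by camera on these same differences. The loci of these 2 lists also had estimated correlations of 0.32 and 0.095, which random lists need not share. The percentiles therefore cannot decide whether largely covered loci gained less. With equal covered length 0 of the 8 lists was called lower, which leaves more called bases in the cKO lists open as the cause. The medians of radial glia, intermediate progenitor and Notch genes then lay near 0 (0.022, 0.024 and 0.0015), and those of deep layer (−0.0087), Wnt (−0.030) and oligodendrocyte precursor and astrocyte genes (−0.065) moved toward 0. Upper layer genes stayed at −0.17 (−0.19 before) and newborn neuron genes at −0.15 (−0.18 before). The SD over members rose from 0.171 to 0.938 for upper layer, from 0.171 to 0.481 for newborn neuron, from 0.170 to 0.873 for deep layer, from 0.190 to 0.508 for Wnt and from 0.161 to 1.07 for oligodendrocyte precursor and astrocyte genes. For upper layer and newborn neuron genes the lost calls went with a wider spread at a similar median and do not speak for called length. For deep layer, Wnt, and oligodendrocyte precursor and astrocyte genes the median shrank and the spread widened together, so their lost calls do not decide. The design cannot separate called length from genotype, because both cKO lists are the longer ones.

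The third pattern is the higher coverage of Pdzrn3 in cKO. Its log2 difference lay at percentile 99.2 of the 500 loci nearest in mean covered length, which argues against a gain shared by loci of like coverage. With equal covered length it was 0.42, or 5.47 times its standard error. That cut kept only peaks of higher −log10 q-value in the cKO lists than in WT. It also moved Prdm16 from −0.14 to 0.16 ± 0.047 (SE). The test therefore cannot decide whether more called bases in the cKO lists caused the Pdzrn3 difference. A genotype effect at this locus remains a hypothesis, found with 2 libraries per genotype and not past the threshold over all loci. Read counts would be needed to test it.

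Chromosome X held 1.08% ± 0.0122 of covered bases in cKO and 0.900% ± 0.0447 in WT (SD, n = 2 each), and 0.565% and 0.792% with equal covered length. No library had a peak on chromosome Y (0 in each list). Meningeal genes, with a median of −0.15 in the lists as deposited, had −0.39 with equal covered length (camera adjusted p = 0.0105, preset correlation). In the lists as deposited they were not called (camera adjusted p = 0.396, and 0.709 with an estimated correlation, fry adjusted p = 0.417). The estimated correlation and fry were not run with equal covered length.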
